A study of Arabidopsis thaliana with 6 samples.

How the data were processed

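RNA was measured in whole Arabidopsis thaliana seedlings of the Columbia genotype. Per the labels' protocols, seedlings spent 3 d in darkness with or without 0.7 ppm ethylene and then 5 d in light without ethylene. There were 3 samples pretreated in air and 3 pretreated with ethylene. Per the labels' protocols, RNA was extracted with Trizol, messenger RNA was enriched and fragmented, and cDNA made by random priming was ligated to adaptors, amplified and sequenced. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

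The authors deposited 1 table of whole-number read counts per transcript for each sample. The aligner, the counting program, the genome build, the annotation version and the use of strand were not given in the sources used here. The tables hold 54013 plant transcript identifiers and 92 ERCC spike-in RNAs, which are synthetic RNAs of known sequence. How and in what amount the spike-ins were added was not given in the sources used here. The authors also deposited a comparison of ethylene with air per transcript, holding log2 fold changes, p-values and adjusted p-values, per the file headers. The 6 per-sample columns of the authors' deposited table are a signal equal to the transcript counts divided by 1 factor per sample. In that table the columns named for air replicates 1 and 3 hold the counts deposited under the other's name. Both are air samples, so the contrast between groups does not depend on which name is right. The significant list among the deposited tables keeps transcripts at an adjusted p of at most 0.05 with at least a 2-fold change, per the file headers.

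Counts were summed over transcripts to 32833 loci, and 325 identifiers written in lower case without an isoform number were joined to their locus. Gene symbols were taken from a RefSeq table of assembly TAIR10.1, which matched 32548 loci. The build behind the counts was not stated, so no coordinates are printed. Spike-in counts were kept out of library sizes and tests. Over protein-coding loci, the median of the mean count per library fell with the number of transcripts in the files, from 75.2 for 1 transcript to 25.2 for 2 and 9.83 for 6 or more. Loci with several transcripts may therefore be counted only from reads that tell the transcripts apart, and their levels are not comparable with those of other loci. Loci that share reads with close paralogs were treated as uncertain, because the handling of shared reads is unknown.

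Total counts ranged from 13163499 to 17462603 per library and plant counts from 12870604 to 17116359, so 1 count corresponded to between 0.0584 and 0.0777 CPM, the usual depth-scaled unit computed by edgeR. The test of change was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) with TMM factors, filterByExpr at its defaults (minimum count 10, minimum total 15), a design with the group alone, and Benjamini-Hochberg (BH) adjustment over all 17887 loci tested. A gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the fold change and the p-value of the test. CPM values are TMM-scaled unless stated otherwise, with the standard deviation (SD) over 3 libraries. DESeq2 1.42.0 was the alternative test.

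There were 30 gene lists with 457 loci, 24 of pathways and responses and 6 of organ or cell type markers. The pathway lists covered the Calvin-Benson cycle, light harvesting and photosystems, chlorophyll synthesis, starch synthesis, starch breakdown, sucrose metabolism and sugar transport, trehalose 6-phosphate metabolism, sugar starvation markers, nitrogen assimilation, ethylene synthesis, ethylene signalling and response, auxin response, cytokinin response, flavonoid and anthocyanin synthesis, glucosinolate synthesis, cold, drought and abscisic acid response, heat shock response, salicylic acid defence, jasmonate response, cell wall expansion, cell division, the circadian clock, glycolysis with organic acids and respiration, and iron and phosphate supply. The marker lists covered root, guard cell and stomatal lineage, xylem, phloem, shoot meristem and young leaf, and seed storage. Each list was tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with BH adjustment over the 30 lists. Camera with an estimated correlation and fry were alternatives. The lists, tests, alternatives and rule for named genes were fixed before the data were examined.

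The rule took the 10 largest rises and 10 largest falls among called genes whose 3 ethylene libraries all lay on one side of the 3 air libraries and whose mean CPM over all 6 libraries was at least 5. From each list it took up to 3 called members with the smallest p and the member with the highest mean CPM. It always took ETR2, ERS2, EBF2, EFE, ERF1, RBCS1A, RCA, LHCB1.1, ADG1, APL3, SEX1, SUC2, SWEET11, SWEET12, DIN6, TPS1, CCA1 and TOC1. Genes without a symbol were named by their locus. Any other gene is said to have been chosen after its values were seen. The result of 1 gene taken by the rule is not reported here.

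Alternatives fixed at that time were RLE and upper-quartile factors, DESeq2, no filter, a filter at a mean CPM of 5, the replicate number as a block, the removal of organelle genes, and leaving out each library in turn. Alternatives chosen after the data were seen were scaling on the spike-in totals, loci with 1 transcript only, and transcripts in place of loci. Shares of counts per library were compared by exact two-sided permutation tests, for which 3 against 3 samples allow no p below 0.1. The fitting step was tested on simulated data in 10 simulations of this comparison with 17887 loci, of which 200 were changed in each. It recovered 27.6% of loci changed 1.5-fold, 60.8% at 2-fold, 90.6% at 4-fold and 95.8% at 8-fold, and 137 of 1511 calls (9.07%) were false. The share of false calls in those simulations was above the nominal 5%. The simulations changed far fewer loci than the 5835 called in the data, so these shares may not carry over to the real fit.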

Results

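Transcript levels were compared between 8-day-old seedlings that had been exposed to ethylene during germination in darkness and seedlings that had germinated in air. The series title speaks of metabolic priming by ethylene, and the comparison asks which transcripts still differed 5 d after the gas was removed. Each group had 3 libraries. Plant counts were 15278372, 12870604 and 14038341 in air replicates 1 to 3 and 14805466, 15973885 and 17116359 in ethylene replicates 1 to 3. The first principal component of log2 CPM carried 64.7% of the variance and separated the groups, and air replicate 3 lay farthest out among the air libraries. No replicate pair agreed within sampling noise, with chi-square values per degree of freedom from 5.22 to 29.5.

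Seedlings pretreated with ethylene had lower levels of transcripts that mark sugar starvation. Transcripts for glucosinolate and flavonoid synthesis, for cell division and for xylem markers were higher. However, no list was called with an estimated correlation between genes, a change whose cause was not tested. DIN2, a beta-glucosidase gene induced in darkness, fell by 4.93 ± 0.34 on the log2 scale (SE, n = 3 per group), from 12.2 ± 3.68 to 0.390 ± 0.115 CPM. CYP79F1, which acts on chain-elongated methionine in glucosinolate synthesis, rose by 2.27 ± 0.21, from 25.1 ± 8.93 to 121 ± 10.8 CPM. Transcripts of the photosynthetic antenna and photosystems made up a smaller part of the messenger RNA, with PSAF of photosystem I falling by 1.19 ± 0.08. KN, which encodes the cytokinesis syntaxin KNOLLE, rose by 1.18 ± 0.13.

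In all, 5835 of 17887 loci were called by edgeR's quasi-likelihood test with BH adjustment, 2828 higher and 3007 lower after ethylene. At least a 2-fold change was seen in 2002 loci, of which 1177 were higher and 825 lower, or 737 and 702 without air replicate 3. In 8536 loci (47.7%, against 10% by chance) the 3 libraries of one group all lay on one side of the other group, and these included 5763 of the called loci. The direction of the small changes depended on the scaling. Spike-in counts per TMM-scaled library were lower in the ethylene libraries by -0.45 on the log2 scale (SD 0.09 in air and 0.20 in ethylene, n = 3 each). Scaling on the spike-ins, chosen after the data were seen, moved the median log2 fold change of all loci from 0.02 to 0.47 and gave 7160 loci higher and 829 lower, with 3252 higher and 408 lower at 2-fold. All changes below are relative to the TMM scale, on which a fall smaller than about the 0.45 shift becomes a rise or no change with spike-in scaling. Some larger falls also lost their call with that scaling, among them most of those in light harvesting and photosystems.

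Among the 10 largest rises, AT5G38910, annotated as a cupin family protein, rose by 4.15 ± 0.29, from 1.13 ± 0.329 to 20.2 ± 5.40 CPM. GSTF14, a glutathione transferase gene, rose by 3.76 ± 0.59, and SESA5, a seed storage albumin gene, by 3.41 ± 0.52. AT3G02480, annotated as a late embryogenesis abundant protein, had 28.2 ± 15.9 CPM in air and 251 ± 56.5 CPM after ethylene. The other rises were AT1G31690 (3.19), AT3G28510 (2.97), AT2G47880 (2.82), AT1G52060 (2.78), PDF2.1 (2.72) and AT1G07560 (2.66), all as log2 fold changes. Among the 10 largest falls, AT2G33160, annotated as a polygalacturonase, had 453 counts over the air libraries and 3 over the ethylene libraries, a ratio of 191.9 with an exact 95% counting interval from 65.3 to 934. That interval covers counting noise alone and leaves out the spread between libraries. AT1G19530 dropped by 6.52 ± 0.30, from 139.7 ± 38.6 to 1.54 ± 0.792 CPM, and AT4G37220, annotated in the WCOR413 cold acclimation family, dropped by 5.74 ± 0.45. NAS3, a nicotianamine synthase gene, had a log2 fold change of -4.28, ATL8 -3.73, AT4G39675 -3.52, PSK2, a phytosulfokine precursor gene, -3.50 and NEET, an iron-sulfur protein gene, -3.47. BCAT-2 and DIN2 completed the falls. All 20 had adjusted p-values of 0.00133 or less in edgeR with BH adjustment, and in each all 3 ethylene libraries lay on one side of the air libraries.

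Sugar starvation markers, genes that respond to darkness or carbon shortage, formed the list with the largest fall. Of 12 members tested, 11 were lower over all genes tested and 11 when adjusted over the list alone, with a median log2 fold change of -2.10. BCAT-2, a branched-chain aminotransferase gene, fell by 5.23 ± 0.42 and IVD, isovaleryl-CoA dehydrogenase, by 1.54 ± 0.13, from 202 ± 35.3 to 69.3 ± 6.27 CPM. DIN6, an asparagine synthetase gene, had 45 counts in air and 4 after ethylene and fell by 3.69 ± 0.72. Camera with BH adjustment called the list (adjusted p = 1.42e-07), with adjusted p = 0.476 with an estimated correlation, and 10 members were lower with spike-in scaling. On loci with 1 transcript the list was not called by camera (adjusted p = 0.108), where 3 members were left, 2 of them lower, with a median of -0.95.

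Members of 3 further carbon and nitrogen lists moved in both directions, and camera with BH adjustment called none of these lists on the TMM scale. In trehalose 6-phosphate metabolism, 5 of 16 members fell and 2 rose, the same numbers adjusted over the list alone, with camera adjusted p = 0.122 and BH adjustment. With spike-in scaling 5 were lower and 3 higher, and camera called the list down relative to other genes (adjusted p = 0.00390 with BH). TPS11 fell by 2.36 ± 0.13, TPS8 by 1.78 ± 0.15 and TPS9 by 1.33 ± 0.09, all of the class II trehalose phosphate synthase proteins, whereas TPS1, the active synthase, rose by 0.55 ± 0.16. In this list 0 members were higher without air replicate 1, air replicate 3, ethylene replicate 1 or ethylene replicate 2, and 1 without ethylene replicate 3. The TPS1 call was lost when air replicate 1, air replicate 3, ethylene replicate 1 or ethylene replicate 2 was left out (edgeR adjusted p with BH from 0.0574 to 0.0978). In sucrose metabolism and sugar transport, 8 of 25 members fell and 3 rose, or 8 and 6 adjusted over the list alone (camera adjusted p = 0.554 with BH), but 4 were lower and 12 higher with spike-in scaling and 7 and 6 with upper-quartile factors. The hexose carriers STP1 and STP13 fell by 1.41 ± 0.11 and 1.37 ± 0.13, and CYFBP, cytosolic fructose-bisphosphatase, fell by 0.91 ± 0.09. SWEET12, a sucrose exporter gene, rose by 0.52 ± 0.11, while SWEET11 had a log2 fold change of 0.04 ± 0.08 and SUC2 of 0.23 ± 0.08, neither past the test with TMM scaling. The list's median was 0.02 and its mean -0.12, and the median was -0.17 without air replicate 3, -0.14 without ethylene replicate 1 and -0.10 without ethylene replicate 2. In nitrogen assimilation, 7 of 14 members fell and 4 rose, the same adjusted over the list alone (camera adjusted p = 0.182 with BH), and 2 were lower with spike-in scaling. The nitrate reductase genes NIA1 and NIA2 fell by 1.37 ± 0.13 and 1.07 ± 0.09, and GLN1;3, a cytosolic glutamine synthetase gene, rose by 0.84 ± 0.11.

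Light harvesting and photosystem transcripts were lower relative to the bulk of the messenger RNA. Of 21 members, 18 fell, or 19 adjusted over the list alone, with a median of -0.57, but with spike-in scaling 1 was lower and 1 higher. PSBR fell by 0.88 ± 0.08, LHCA3 by 0.82 ± 0.08 and CAB1 by 0.65 ± 0.07 on the TMM scale, and none of these 3 was called with spike-in scaling. CAB1 was the most abundant member, at 27686 ± 1213 CPM in air and 17638 ± 390.1 after ethylene. LHCB1.1 fell by 0.85 ± 0.09, not called with spike-in scaling, but its counts and those of CAB1 are uncertain because the 2 genes are near-identical. The list was called by camera with BH adjustment (adjusted p = 5.65e-08), with adjusted p = 0.476 with an estimated correlation. The Calvin-Benson list had 6 of 18 members lower, the same adjusted over the list alone, and a median of -0.21. With spike-in scaling the median became 0.25, with 1 member lower and 2 higher. RPE, ribulose-phosphate epimerase, fell by 1.36 ± 0.11, CP12-1 by 0.83 ± 0.09 and GAPA-2 by 0.62 ± 0.11, the last 2 not called with spike-in scaling. RBCS1A, a small subunit gene of Rubisco whose reads may be shared with its paralogs, had a log2 fold change of -0.23 ± 0.09 (edgeR adjusted p = 0.0867 with BH), and RCA of -0.13 ± 0.09. The RBCS1A call was gained when air replicate 2 or ethylene replicate 1 was left out. After BH adjustment camera gave adjusted p = 0.0105, with adjusted p = 0.476 with an estimated correlation, and the call was lost with spike-in scaling (0.155) and on loci with 1 transcript (0.119), where 4 of 8 were lower with a median of -0.24. In chlorophyll synthesis, 7 of 17 members fell and 2 rose, or 8 and 2 adjusted over the list alone. The median moved from -0.19 to 0.25 with spike-in scaling, where 1 was lower and 3 higher. HEMA1, encoding glutamyl-tRNA reductase, the first committed enzyme of the pathway, fell by 2.44 ± 0.12, from 929.6 ± 139.9 to 171 ± 12.7 CPM. GUN5 fell by 0.78 ± 0.09 and CHLI1 by 0.34 ± 0.08 on the TMM scale, neither called with spike-in scaling, where CHLI1 had a log2 fold change of 0.12, while PORC rose by 0.57 ± 0.11. Leaving out 1 library left 1 member higher and 4 to 8 lower, with 4 without air replicate 3 and 4 without ethylene replicate 3. The camera test with BH adjustment gave adjusted p = 0.0478, with adjusted p = 0.513 with an estimated correlation, 0.0749 without air replicate 3, 0.102 without ethylene replicate 3, 0.155 with spike-in scaling, 0.0773 with a filter at a mean CPM of 5 and 0.0825 on loci with 1 transcript, where the median was -0.38.

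Starch genes moved in both directions on the TMM scale, but none was called lower with spike-in scaling. In starch synthesis, 3 of 16 members rose and 2 fell, the same adjusted over the list alone and 7 and 0 with spike-in scaling, with a median of -0.01 and a mean of 0.11 (camera adjusted p = 0.918 with BH). GBSS1, granule-bound starch synthase, rose by 1.16 ± 0.20 and APL3, a large subunit of ADP-glucose pyrophosphorylase, rose from 3.13 ± 0.468 to 6.71 ± 1.16 CPM. SS4 fell by 0.76 ± 0.09 on the TMM scale and was not called with spike-in scaling. The small subunit gene ADG1 was at 756 ± 49.6 CPM in air and 758 ± 49.0 after ethylene, and ADG2 fell by 0.44 ± 0.08 on the TMM scale but had a log2 fold change of 0.02 with spike-in scaling. In starch breakdown, 4 of 16 members rose and 3 fell, the same adjusted over the list alone and 9 and 0 with spike-in scaling (camera adjusted p = 0.621 with BH). LSF2 rose by 0.82 ± 0.12 and ISA3 by 0.47 ± 0.08. AMY3 fell by 0.45 ± 0.08, a change of 0.01 with spike-in scaling, and PHS1 had a log2 fold change of -0.02 ± 0.08. SEX1 had between 1 and 17 counts per library and was not tested. In glycolysis, organic acids and respiration, 4 of 13 members rose and none fell, the same adjusted over the list alone. These included PPC3, a phosphoenolpyruvate carboxylase gene, by 1.73 ± 0.31, HXK1 by 0.74 ± 0.12 and GAPC1 by 0.66 ± 0.11. With spike-in scaling 11 members of this list rose, and the median moved from 0.36 to 0.82. Camera with BH adjustment called the list (adjusted p = 0.0208), with adjusted p = 0.476 with an estimated correlation, and with 0.0521 with spike-in scaling, 0.0657 with no filter on low counts and 0.0890 on loci with 1 transcript, where the median was 0.47.

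**Figure D1:**
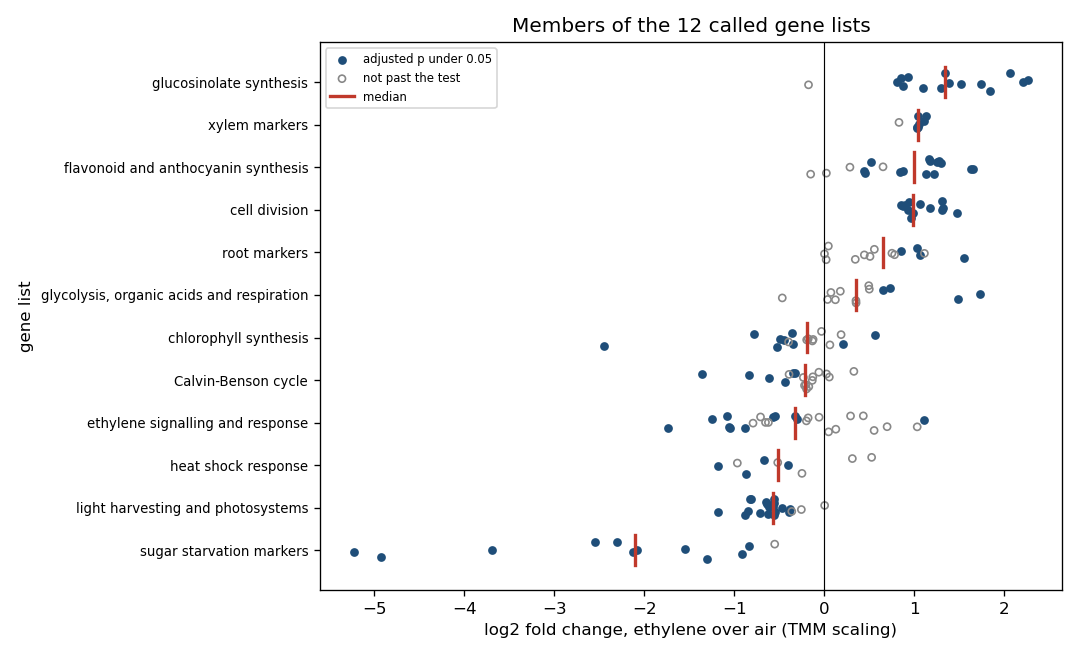
Log2 fold changes (ethylene over air, TMM scaling, x axis) of the members of the 12 gene lists called by camera (y axis). Filled points passed edgeR's test over all genes, open points did not, and vertical bars are list medians, from -2.10 for sugar starvation markers to 1.34 for glucosinolate synthesis. With spike-in scaling the medians of the Calvin-Benson, chlorophyll and ethylene signalling lists were above 0.

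Genes of the ethylene pathway itself differed after 5 d without the gas. In ethylene signalling and response, 10 of 25 members fell and 1 rose, or 11 and 5 adjusted over the list alone, and the median moved from -0.32 to 0.12 with spike-in scaling, where 5 were lower and 8 higher. RAV1 fell by 1.74 ± 0.14, TEM1 by 1.25 ± 0.10 and EBF2, an F-box gene that acts on the regulator EIN3, by 0.88 ± 0.09. The receptor gene ETR2 fell by 1.05 ± 0.36 (edgeR adjusted p = 0.0491 with BH), a call lost with upper-quartile factors, with spike-in scaling and without air replicate 2, air replicate 3, ethylene replicate 1 or ethylene replicate 2 (adjusted p 0.117, 0.104, 0.145 and 0.146). ERS2 had a log2 fold change of -0.62 ± 0.43 and EIN2 of 0.13 ± 0.07, neither past the test on the TMM scale, and ERF1 had at most 6 counts per library and was not tested. After BH adjustment camera gave adjusted p = 0.0358 for the list, with adjusted p = 0.476 with an estimated correlation, and 0.0978 without air replicate 2, 0.0509 without ethylene replicate 1, 0.143 with a filter at a mean CPM of 5 and 0.130 on loci with 1 transcript, where the median was -0.28. In ethylene synthesis, 6 of 12 members fell and 2 rose, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.142 with BH). With spike-in scaling the median moved from -0.44 to 0.02, and 5 were lower and 4 higher. There camera called the list down relative to other genes, whose median had risen (adjusted p = 0.00795 with BH). The ACC synthase genes ACS8 and ACS11 fell by 3.21 ± 0.34 and 2.01 ± 0.22. EFE fell by 0.43 ± 0.08 on the TMM scale and had a log2 fold change of 0.02 with spike-in scaling.

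Both secondary metabolite lists were higher after ethylene. In glucosinolate synthesis, 14 of 15 members rose, the same adjusted over the list alone, with a median of 1.34. BCAT4, which starts methionine chain elongation, rose by 2.21 ± 0.25, SOT18 by 1.30 ± 0.16 and CYP83A1 by 1.74 ± 0.23, the last from 169.8 ± 62.1 to 567 ± 45.7 CPM. CYP79F1 shares sequence with its neighbour CYP79F2, so its value is uncertain. In flavonoid and anthocyanin synthesis, 14 of 18 members rose and none fell, or 16 adjusted over the list alone, with a median of 1.00. The regulators TT8 and MYB111 rose by 1.65 ± 0.25 and 1.27 ± 0.24, FLS1, flavonol synthase, by 1.13 ± 0.15, and TT4, chalcone synthase, by 0.87 ± 0.22. The camera test with BH adjustment called both lists (adjusted p = 1.02e-06 and 0.000123), with adjusted p = 0.476 and 0.478 with an estimated correlation. Leaving out 1 library left 14 glucosinolate genes higher and 9 to 15 flavonoid genes, with 9 without ethylene replicate 2.

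Cell division genes rose as a group, with 13 of 13 tested members higher over all genes tested, the same adjusted over the list alone and with spike-in scaling, and a median of 0.99. HIK, a kinesin gene, rose by 1.31 ± 0.14 and PCNA2, a sliding clamp gene of DNA replication, by 0.97 ± 0.10. Camera with BH adjustment gave adjusted p = 5.92e-08, with adjusted p = 0.476 with an estimated correlation. Xylem markers behaved alike, with 7 of 8 higher, or 8 adjusted over the list alone, and a median of 1.05. LAC4 rose by 1.13 ± 0.14, the secondary wall cellulose synthase genes IRX3 and IRX1 by 1.05 ± 0.12 and 1.05 ± 0.14, and the protease gene XCP2 by 1.05 ± 0.15. After BH adjustment camera gave adjusted p = 0.000168, with adjusted p = 0.476 with an estimated correlation.

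Among the other marker lists, 4 of 14 root markers were higher and none lower, or 5 adjusted over the list alone, with a median of 0.66. With spike-in scaling 11 root markers were higher, with a median of 1.13. TIP2;3, an aquaporin gene, rose by 1.56 ± 0.23, PHO1 by 1.03 ± 0.16 and CASP2 by 0.85 ± 0.23, the CASP2 call being lost without air replicate 1 or ethylene replicate 1 (edgeR adjusted p = 0.0700 and 0.0603 with BH). PYK10, by far the most abundant root marker, was at 5699.9 ± 881 CPM in air and 5791 ± 519 after ethylene. The camera test with BH adjustment called the list (adjusted p = 0.0191), with adjusted p = 0.513 with an estimated correlation and 0.0582 without air replicate 3, where the median was 0.34. Fry did not call the root list (adjusted p = 0.124 with BH). Without air replicate 1 or ethylene replicate 1, 2 root markers were higher, and without air replicate 2, 7 were. In the guard cell list 1 of 8 rose, KAT1 by 0.86 ± 0.20, and the same 1 was counted adjusted over the list alone, while TMM had a log2 fold change of 0.05 ± 0.10 (camera adjusted p = 0.454 with BH). With spike-in scaling 5 guard cell markers rose, and the list's median moved from 0.17 to 0.63. In the phloem list 2 of 5 rose, the same adjusted over the list alone, SEOR1 by 0.73 ± 0.12 and PP2-A1 by 0.35 ± 0.09 (camera adjusted p = 0.156 with BH). The PP2-A1 call was lost without air replicate 1 or ethylene replicate 1 (edgeR adjusted p = 0.0679 and 0.0608 with BH). In the shoot meristem and young leaf list 2 of 6 rose and 1 fell, or 2 and 2 adjusted over the list alone and 2 and 0 with spike-in scaling (camera adjusted p = 0.746 with BH). ANT rose by 0.70 ± 0.13 and GRF5 by 0.93 ± 0.28, and KNAT1 fell by 0.88 ± 0.14, not called with spike-in scaling. In this list 1 member was higher when any library but air replicate 2 was left out, and 2 were lower without air replicate 3. The GRF5 call was lost without any one of air replicates 1 and 3 and ethylene replicates 1, 2 and 3 (edgeR adjusted p with BH from 0.0506 to 0.105). Of 8 seed storage markers only SESA2 was tested. It rose by 2.07 ± 0.62, also adjusted over the list alone (camera adjusted p = 0.454 with BH), a call lost without any one ethylene library and with DESeq2 (adjusted p = 0.216 with BH).

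**Figure D2:**
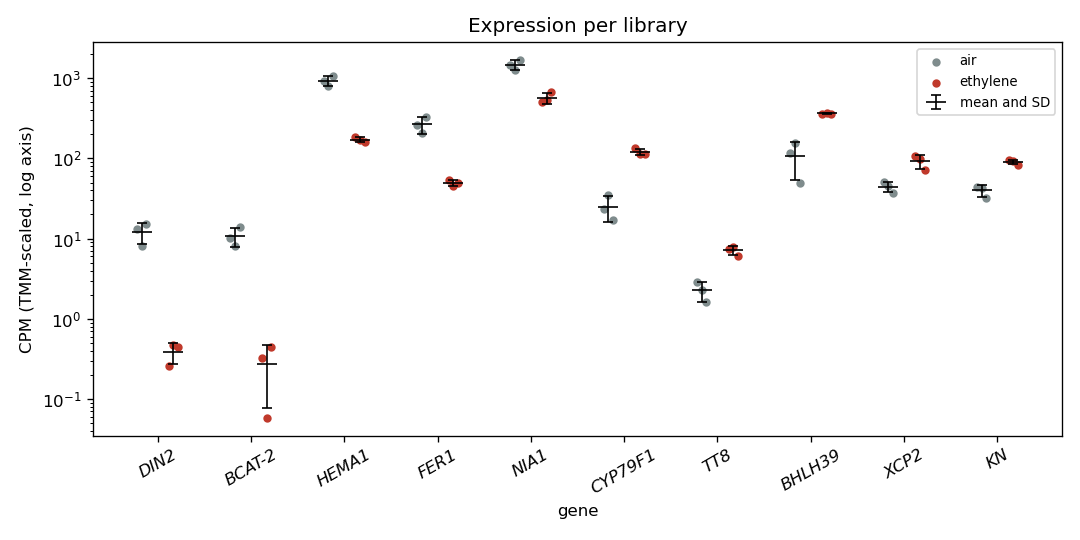
TMM-scaled CPM (log axis) of 10 genes in each library, with means and SD (n = 3 per group, air in grey and ethylene in red). For each gene the 3 ethylene libraries lay on one side of the 3 air libraries, such as FER1 at 267 ± 62.8 CPM in air and 49.5 ± 4.21 after ethylene.

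In the iron and phosphate list, 9 of 14 members rose and 3 fell, the same adjusted over the list alone, with camera adjusted p = 0.118 and BH adjustment. BHLH39 and BHLH101, regulators induced by iron deficiency, rose by 1.77 ± 0.31 and 1.36 ± 0.18. The ferritin genes FER1 and FER4, which encode iron storage proteins, fell by 2.43 ± 0.16 and 2.38 ± 0.17. In cell wall expansion, 4 of 13 members rose and 4 fell, or 6 and 4 adjusted over the list alone and 7 and 2 with spike-in scaling. XTH24 fell by 2.81 ± 0.17, from 1895 ± 346 to 270.0 ± 57.9 CPM, and TCH4 by 2.96 ± 0.19, while EXPA4, an expansin gene, rose by 1.23 ± 0.15. In this list 2 were higher without air replicate 1 and 1 without ethylene replicate 1, and the median without air replicate 3 was 0.17. The list's median was 0.29, its mean -0.27, camera's direction was up (adjusted p = 0.976 with BH) and fry's was down (adjusted p = 0.0141 with BH).

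Of the hormone and stress lists, heat shock response was called as a group on the TMM scale (camera adjusted p = 0.0358 with BH), with adjusted p = 0.476 with an estimated correlation. In this list, 4 of 9 members fell, or 5 adjusted over the list alone, with a median of -0.52, and with spike-in scaling 1 was lower and 1 higher. HSFA7A fell by 1.18 ± 0.12, HSP70 by 0.87 ± 0.11 and HSP90.1 by 0.41 ± 0.10 on the TMM scale, the last 2 not called with spike-in scaling, where HSP90.1 had a log2 fold change of 0.05. The list call was lost without ethylene replicate 2 (camera adjusted p = 0.0616 with BH) and, at 0.130, on loci with 1 transcript, where the median was -0.55. In auxin response, 4 of 10 rose and 1 fell, or 6 and 2 adjusted over the list alone and 8 and 1 with spike-in scaling (camera adjusted p = 0.182 with BH). GH3.3 rose by 0.92 ± 0.13, GH3.5 fell by 0.94 ± 0.12, and PIN3 had a log2 fold change of -0.20 ± 0.08. IAA19 rose by 0.91 ± 0.28, a call lost without air replicate 1, air replicate 3, ethylene replicate 1 or ethylene replicate 3 (edgeR adjusted p with BH from 0.0834 to 0.116). In this list 1 member was higher without air replicate 1, air replicate 3, ethylene replicate 1 or ethylene replicate 3, and 2 without ethylene replicate 2. In cytokinin response, 3 of 10 rose, or 5 with 1 lower adjusted over the list alone (camera adjusted p = 0.0808 with BH, and 0.0423 without air replicate 2). With spike-in scaling 6 cytokinin members rose, and the median moved from 0.39 to 0.87. In this list 1 member was higher without air replicate 1 or ethylene replicate 2. ARR8 rose by 0.65 ± 0.16, and the calls of CRF2 and ARR15 (log2 fold changes 0.60 and 1.41) were each lost when single libraries were left out, CRF2 without air replicates 1 or 3 or ethylene replicate 2 and ARR15 without air replicates 1 or 2 or ethylene replicates 1 or 2 (edgeR adjusted p with BH from 0.0505 to 0.142). In cold, drought and abscisic acid response, 3 of 14 fell, the same adjusted over the list alone, while 1 was lower and 5 higher with spike-in scaling (camera adjusted p = 0.345 with BH), with a median of 0.01, which was -0.38 without ethylene replicate 3 and -0.18 without air replicate 3, and a mean of -0.27. RD22 fell by 0.53 ± 0.09 and DREB2A by 0.59 ± 0.14, neither called with spike-in scaling, and RD29B by 1.92 ± 0.49, lost without air replicate 1, ethylene replicate 1 or ethylene replicate 2 (edgeR adjusted p = 0.0761, 0.0509 and 0.0577 with BH). In salicylic acid defence, 4 of 10 rose and 2 fell, or 5 and 3 adjusted over the list alone and 7 and 0 with spike-in scaling (camera adjusted p = 0.328 with BH). ALD1, which acts in pipecolic acid synthesis, rose from 0.564 ± 0.223 to 5.53 ± 0.809 CPM and WRKY54 by 1.85 ± 0.35, while NPR1 fell by 0.37 ± 0.08 on the TMM scale and had a log2 fold change of 0.09 with spike-in scaling. In jasmonate response, 2 of 11 rose, the same adjusted over the list alone, AOC3 by 1.14 ± 0.24 and AOS by 0.91 ± 0.13 (camera adjusted p = 0.590 with BH, median -0.04, mean 0.16).

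Of 12 clock genes 6 were lower and 3 higher, the same adjusted over the list alone (camera adjusted p = 0.229 with BH), and 2 lower with spike-in scaling. Leaving out 1 library left 6 lower, with 2 higher without air replicate 2 or ethylene replicate 1 and 1 higher without any of the other 4 libraries. PRR5 fell by 1.14 ± 0.10, FKF1 by 0.99 ± 0.13 and GI by 0.66 ± 0.09, the last not called with spike-in scaling, and the glycine-rich protein gene CCR2 rose by 0.54 ± 0.09. TOC1 fell by 0.37 ± 0.08 on the TMM scale and had a log2 fold change of 0.08 with spike-in scaling. CCA1 rose by 0.54 ± 0.18 (edgeR adjusted p = 0.0469 with BH), a call lost with DESeq2, with no filter and without air replicates 1, 2 or 3 or ethylene replicates 2 or 3 (adjusted p from 0.0508 to 0.137).

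Camera called 12 of the 30 lists, 6 up and 6 down, after BH adjustment, against 0 with an estimated correlation and 20 with fry, which does not compare a list with other genes. Across all loci tested, 15.8% were higher and 16.8% lower.

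Library composition differed within the ethylene group. Chloroplast genes took 1.45% ± 0.05 of plant counts in air and 1.48% ± 0.38 after ethylene (SD, n = 3 each, exact two-sided permutation p = 1.0). Mitochondrial genes took 0.0746% ± 0.0194 and 0.274% ± 0.172 (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow), and the difference of 0.200 percentage points became 0.101 without ethylene replicate 3. Most of these counts were ribosomal RNA. The 2 mitochondrial ribosomal RNA loci took 0.0553% of plant counts in air and 0.231% after ethylene, and made up 0.176 of the 0.200 percentage points. Ethylene replicate 3 held 361271 counts of nuclear 18S ribosomal RNA, against 21814 to 36318 in the other 5 libraries. Without that library 4842 loci were called, and 2006 at 2-fold.

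**Figure D3:**
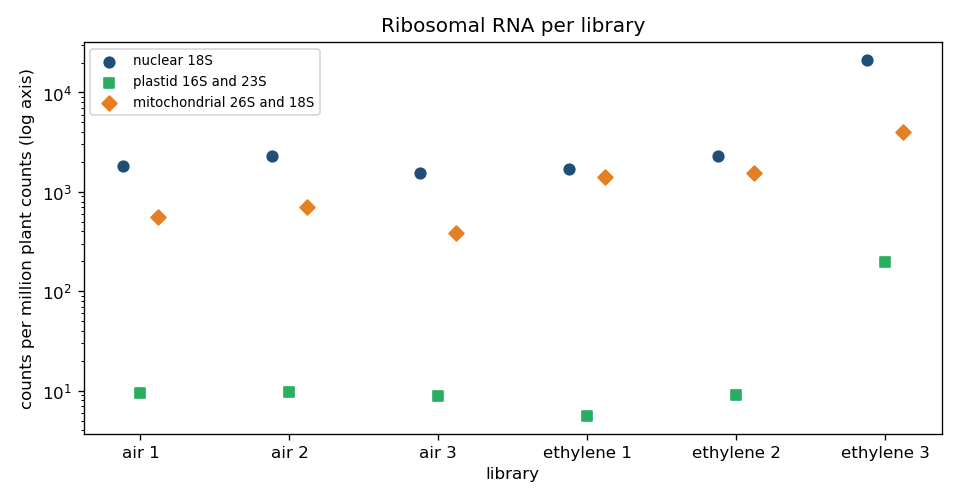
Ribosomal RNA CPM without TMM scaling (log axis) in each of the 6 libraries (x axis), for nuclear 18S, plastid 16S and 23S, and mitochondrial 26S and 18S loci. Ethylene replicate 3 was highest in each class, at 9.11, 20.7 and 2.58 times the next library.

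The authors' deposited table gave 5628 of 18939 transcripts at an adjusted p of at most 0.05, and the authors' deposited significant list held 1985 transcripts, 1114 higher and 871 lower, from 1937 plant loci. Of the 2002 loci called here at 2-fold by edgeR, 1797 were in that list, all with the same sign. The list was made from these same libraries and is not independent evidence. It also holds 1 spike-in, and 52 of the 53 spike-ins in the authors' deposited table had negative log2 fold changes, with a median of -0.39.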

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

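Spike-in scaling, loci with 1 transcript and transcripts in place of loci were alternatives chosen only after the data were seen. The count of genes called kept within 1.5 times of 5835 under RLE and upper-quartile factors, DESeq2, both filters, the removal of organelle genes, spike-in scaling, single-transcript loci and transcripts. No shared call changed sign in the settings that test loci. A similar count did not mean the same genes, because spike-in scaling kept only 3654 of the 5835 calls. Of its 7989 calls, 7160 were higher and 829 lower. Leaving out 1 library gave 4361 to 5903 genes, 1439 to 2414 at 2-fold and 10 to 12 lists, and chloroplast share differences (ethylene minus air) of -0.176 (without ethylene replicate 3) to 0.196 percentage points (without ethylene replicate 1). The count at 2-fold was 1157 with a mean CPM filter of 5, which tests fewer genes, and 3660 with spike-in scaling, which raised the median log2 fold change of all loci by 0.45. The 12 lists became 6 on single-transcript loci, 0 with an estimated correlation and 20 with fry. In ethylene signalling and response the estimated correlation of 0.0057 lay below the preset 0.01, yet camera's adjusted p with BH rose from 0.0358 to 0.476. That list's own correlation therefore does not account for its lost call. The cause of these list changes was otherwise not tested. Of named genes called in either fit, spike-in scaling turned the sign of CHLI1 (0.12), ADG2 (0.0232), AMY3 (0.00670), PHS1 (0.44), HSP90.1 (0.0451), NPR1 (0.0889), EFE (0.0218) and TOC1 (0.0823), and fry turned the cell wall list (adjusted p = 0.0141 with BH). Of 129 named genes, 118 were called, and 11 of these lost their call in at least 1 leave-one-out fit.

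With the replicate number as a block, 5574 genes, 2009 at 2-fold and 11 lists were called, without chlorophyll synthesis (0.0819), and ARR15 (0.0636) and CCA1 (0.0806) were lost (adjusted p with BH). Correlations of same-numbered deviations were 0.02, -0.06 and 0.12, and not every sample correlated best with its own number, though air replicate 3 and ethylene replicate 3 did. These values gave no clear sign of pairing. So few correlations cannot exclude a shared plate or day, and the deposited names of air replicates 1 and 3 are in conflict. In 10 splits of the 6 libraries, too few for a share under 0.05, the real split called 5835 genes, 2002 at 2-fold and 12 lists, and the highest other called 0, 0 and 10. For each of these 3 results, 1 split reached the real value, the real one itself. The other splits called 0 genes but 1, 0, 1, 8, 6, 7, 10, 7 and 5 lists, so many list calls also arose in mixed groupings. Each mixed split still set most air libraries against most ethylene libraries, so part of the real contrast remained and its list calls need not be false. Mixing also puts the group difference into the spread within each side, which makes gene calls unlikely. Neither count therefore estimates false calls. Depth limits genes near the filter. The 1.5-fold changes simulated were mostly missed, but those simulations changed 200 loci, against 5835 called in the data.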

Other observations

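The tests of product families, microRNA precursors, iron genes, ribosomal RNA and spike-ins were chosen only after the data were seen, as were the genes named in this part.

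Other gene families differed in the share of their members that changed. Among 73 families of at least 20 tested loci that share a product description, Fisher's exact tests with BH adjustment over 146 tests gave an excess of higher members for lipid-transfer and 2S albumin proteins (25 of 50 higher, 10 lower, adjusted p = 3.98e-06), histones (16 of 28 higher, 2 lower, adjusted p = 6.26e-05) and peroxidases (21 of 45 higher, 6 lower, adjusted p = 7.36e-05). An excess of lower members was found for alpha/beta-hydrolases (39 of 129 lower, 22 higher, adjusted p = 0.00598) and thioredoxin superfamily proteins (15 of 42 lower, 5 higher, adjusted p = 0.0472). Also past the test were UDP-glycosyltransferases (22 of 63 higher, 12 lower, adjusted p = 0.00602), MtN21/EamA-like transporters (12 of 27 higher, 3 lower, adjusted p = 0.0117), pectin lyase-like proteins (15 of 42 higher, 3 lower, adjusted p = 0.0329), dirigent-like proteins (9 of 20 higher, 2 lower, adjusted p = 0.0405) and FAD/NAD(P)-binding oxidoreductases (9 of 20 lower, 2 higher, adjusted p = 0.0497). These tests treat genes as independent and use TMM-scaled calls. Within the thioredoxin family, AT4G15660, AT4G15670, AT4G15680, AT4G15690 and AT4G15700, close copies with consecutive locus numbers, had log2 fold changes of -2.11, -1.58, -1.11, -1.52 and -1.51. Their values and those of histone genes are uncertain, because the handling of reads shared between close copies is unknown. DOX1, a dioxygenase gene grouped with the peroxidases, was at 337 CPM in air and 1306 after ethylene.

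Of 34 microRNA precursor loci tested, 5 were higher and 2 lower in edgeR with BH adjustment. Across all loci tested, 15.8% were higher and 16.8% lower, and a difference of the precursors from these shares was not tested. The call of MIR169a, 1 of the 5, was lost with DESeq2 (adjusted p = 0.113 with BH). The counts are of precursor transcripts, matched by identifier, and say nothing of mature microRNAs.

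Ribosomal RNA was weighed as a first pattern. In ethylene replicate 3 the nuclear, plastid and mitochondrial classes were each at least 2.58 times the next library, as less complete removal of ribosomal RNA in that library would give. The excess was not confined to ribosomal RNA. The plastid protein genes psbA and rbcL were at 1177 and 762 CPM there, against at most 139 and 121 CPM in any other library. By contrast, the plastid genes atpB and rpl32, at 3974 and 936 CPM, lay below every air library. Incomplete removal of ribosomal RNA alone does not cover psbA and rbcL. In ethylene replicates 1 and 2 mitochondrial ribosomal RNA was 2.58 and 2.79 times the air mean, but plastid ribosomal RNA was 0.594 and 0.981 times the air mean, which argues against incomplete removal there. In edgeR with BH adjustment the mitochondrial ribosomal RNA loci ATMG00020 and ATMG01390 were higher after ethylene (log2 fold changes 1.92 ± 0.32 and 1.85 ± 0.58, adjusted p = 0.00141 and 0.0341), and without ethylene replicate 3 the values were 1.43 and 0.49 (adjusted p = 0.00123 and 0.0462). The ATMG01390 call was lost with DESeq2 (adjusted p = 0.0782 with BH) and without air replicate 1, 2 or 3 (0.0861, 0.0568 and 0.0789), and an effect of the pretreatment stays open.

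Iron-deficiency genes were weighed as a second pattern. The 8 tested genes IRT1, FRO3, BHLH38, BHLH39, BHLH100, BHLH101, IMA1 and PYE had a mean log2 fold change of 1.64 against 0.65 for 14 root markers, a difference of 0.99. The 8 genes were picked after their values were seen, so a larger root share in the ethylene seedlings cannot be told apart from a change within the root by this difference. The median log2 fold change of these 8 genes was at least 1.40 without any one library. Genes picked after their values were seen were likely to pass this test, so it shows only that these 8 did not rest on 1 library. A candidate explanation is a lower iron status of the ethylene seedlings, in keeping with the fall of FER1 and FER4, but seedling iron was not measured here and this stays open.

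The spike-in shift was weighed last. The spike-in share of all counts was 2.08% ± 0.13 in air and 1.72% ± 0.24 after ethylene (SD, n = 3 each, exact two-sided permutation p = 0.2), a log2 ratio of -0.27, and the groups overlapped, so a change in composition cannot be told apart from a change in total messenger RNA by this value. Over 18 spike-ins with a mean count of at least 1000, the log2 shift per spike-in had an SD of 0.0523 and ranged from -0.51 to -0.32. Unequal addition of spike-ins and more messenger RNA per unit of RNA after ethylene predict a shift in the same direction and cannot be told apart, because the amounts added were not given in the sources used here.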
